A study of Homo sapiens with 12 samples.

How the data were processed

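RNA was sequenced from HEK293 cells, a human embryonic kidney line that carries adenoviral E1A and E1B genes, after transfection with 1 of 4 RCAS plasmids, a vector family derived from an avian retrovirus. Per the labels' protocols, 30000 cells were seeded per well of 48-well plates, 300 ng of plasmid was transfected 16 h later, and RNA was isolated 48 h after transfection. Libraries were made with a stranded poly(A) kit (TruSeq Stranded mRNA) and 70 libraries were pooled for sequencing, per the labels' protocols. The inserts were GFP, wild-type YAP1 (wtYAP1), the fusion YAP1-MAML2, and the same fusion with the S94A change (S94A-YAP1-MAML2). There were 12 libraries, 3 in each of the 4 groups, and each was put in its group by its description. Nothing in the sources used here says that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

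The authors deposited 1 table of read counts per gene for each library, made with HTSeq on genome build hg38, per the submitters' processing notes. The names of the deposited tables describe exon counting with reverse strand, so antisense partners were taken as separated. The aligner, the HTSeq version and the annotation release are not given in the sources used here. Each deposited count table held 60483 genes and 5 special counters. These counters (no feature, ambiguous, too low quality, not aligned, not unique) stayed out of library sizes and tests. They held 17.05 to 18.83% of all entries per library, of which reads without a unique position made up 7.57 to 8.36 points. Reads shared between near-identical genes were therefore mostly left out of the gene counts. Some named genes with such copies are marked as uncertain. No search for copies was run, so a gene without that mark may have them too. Gene identifiers were matched to symbols for 56321 of the 60483 genes, and 99.97% of gene counts lay on genes with a symbol. Coordinates are those of GENCODE release 29 on GRCh38, the assembly that the name hg38 stands for, and 56753 identifiers were found in it. Lengths and GC content are those of the longest annotated transcript.

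Library totals ranged from 37517326 to 54873732 gene counts. CPM values are counts per 1e6 with library sizes scaled by TMM. Groups are given as mean ± SD with n = 3. Genes with too few counts were removed with edgeR's filterByExpr on the 4 groups, which left 17457 genes, 17315 of them with a symbol. The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, robust, R 4.3.3) over all 12 libraries with 1 mean per group and 8 residual degrees of freedom. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. All tests were two-sided. Unless another tool is named, adjusted p-values for genes come from this test. The ± or SE of a log2 fold change is the absolute log2 fold change divided by the square root of the test's F. This approximates a standard error, and it can be too small for large changes from few counts. The 5 comparisons were each fusion and wtYAP1 against GFP, YAP1-MAML2 against S94A-YAP1-MAML2, and YAP1-MAML2 against wtYAP1. YAP1 and MAML2 levels were also compared by an exact permutation test, whose smallest two-sided p for 3 against 3 is 0.1. The common biological coefficient of variation was 4.08%. Replicates were compared before averaging. Over the 12 pairs within groups, chi-square per degree of freedom was 3.164 to 8.678 for genes with a summed count of at least 20, so no pair differed by as little as sampling noise.

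There were 25 fixed gene lists. They were YAP/TAZ-TEAD targets (genes on which YAP1 acts through TEAD factors), Hippo pathway and TEAD components, NOTCH targets, CREB targets, AP-1 and immediate early genes, SRF/MRTF cytoskeletal genes, extracellular matrix genes, TGF-beta and BMP response genes, WNT targets, mitosis genes, DNA replication genes, p53 targets, interferon response genes, NF-kappaB targets, unfolded protein and ATF4 response genes, heat shock genes, cholesterol synthesis genes, hypoxia and glycolysis genes, mitochondrially encoded mRNAs, replication-dependent histone genes, and markers of fibroblasts, blood cells, endothelium, keratin epithelium and neurons. Of these, 21 had at least 5 tested members and were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, adjusted over the lists of a comparison). Each camera call was set beside camera with an estimated correlation and beside fry, which tests a list alone and whose adjusted p is given where it ends the call.

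The genes named were chosen by rule. For each comparison these were the 6 largest rises and 6 largest falls with an average log2 CPM of at least 1, a symbol and no overlap between the 2 groups' CPM values. The rule added YAP1 and MAML2, the genes CCN1, CCN2, ANKRD1, AMOTL2, LATS2, HES1, HEY1, NRARP and FOS, and up to 3 called members per direction of each list. For a list with no call it added at most 2 members of highest expression. The groups, tests, lists, this rule and all alternatives but 2 were fixed before the data were examined.

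The alternatives were DESeq2 size factors or library totals in place of TMM, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a stricter filter (CPM of at least 1 in at least 3 libraries), a fit of only the 2 groups compared, the replicate number as a block, removal of YAP1 and MAML2, an adjusted p under 0.01, a 2-fold minimum, and leaving out each library in turn. Removal of a smooth trend of each library on GC content and transcript length was added after seeing the data. It used the 17324 tested genes with both values. DESeq2 gave no adjusted p for 21 of the 197 values of named genes, 13 of them called by edgeR, and these were not counted as lost. Of the 13, 7 were in S94A-YAP1-MAML2 vs GFP, 3 in wtYAP1 vs GFP, 2 in YAP1-MAML2 vs S94A-YAP1-MAML2 and 1 in YAP1-MAML2 vs GFP. DESeq2 with no independent filtering was therefore added, also after seeing the data.

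The tests were tried on simulated counts drawn from the real means and library sizes of 17457 genes, with 200 genes changed, 50 at each fold. For YAP1-MAML2 against GFP, edgeR recovered 38% of genes changed 1.2-fold, 64% at 1.5-fold, 70% at 2-fold and 94% at 4-fold, and 7% of its calls were false. For S94A-YAP1-MAML2 against GFP it recovered 58%, 72%, 72% and 92%, with 2% false calls. For wtYAP1 against GFP it recovered 54%, 76%, 78% and 94%, with 8.5% false calls. With a GC trend added to the simulated YAP1-MAML2 libraries alone, 2498 unchanged genes were called against GFP, and 9 after the trend was removed. The added trend was linear in GC content, which the removal step can fit, so its removal was built in. Its strength was not matched to that in the real data, so 2498 is no scale for false calls there. A list shifted 1.2-fold was called by camera in each of the 5 comparisons, with 0 of the other lists called by camera and 1 called by fry for YAP1-MAML2 against wtYAP1. Simulated genes were drawn independently of each other, so this does not show how often camera calls unchanged lists of correlated genes. In the real data the estimated correlation reached 0.758, for the hypoxia and glycolysis list in YAP1-MAML2 against GFP. Shared calls were set beside 20 simulations per pair of comparisons, added after seeing the data, in which both groups changed on unrelated genes, plasmid genes left unchanged. Tables were made with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.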

Results

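Gene expression was measured by poly(A) RNA-seq in HEK293 cells 48 h after transfection with plasmids for GFP, wild-type YAP1, the gene fusion YAP1-MAML2, or YAP1-MAML2 with the S94A change. YAP1 is a transcriptional coactivator restrained by the Hippo kinases that acts on DNA through TEAD factors, and S94A removes a serine of YAP1 needed for TEAD binding. MAML2 is a NOTCH coactivator that contributes its C-terminal part to the fusion. There were 3 libraries per group. Gene counts per library ranged from 37517326 (GFP replicate 3) to 54873732 (GFP replicate 2). Between 23711 and 25028 genes had at least 1 count in a library, and the 10 most abundant genes held 4.16 to 4.77% of counts. Log2 CPM values of any 2 libraries correlated across genes at 0.9888 to 0.9936. The first principal component, with 16.8% of the variance, set the 3 YAP1-MAML2 libraries apart from the other 9. Mitochondrially encoded RNA took 3.24 to 3.5% of counts in the 6 fusion libraries and 2.63 to 2.88% in the 6 GFP and wtYAP1 libraries. Sample numbers in the names of the deposited tables ran from 50 to 55 for GFP and wtYAP1 and from 62 to 67 for the fusions. Each comparison of a fusion with GFP or wtYAP1 therefore also crosses a possible difference in handling.

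The genes carried by the plasmids were counted first. YAP1 (chromosome 11, 102110461 to 102233423) stood at 50.06 ± 0.593 CPM (SD, n = 3) with GFP and 2423 ± 105 CPM with wtYAP1, a 48.4-fold difference. With YAP1-MAML2 it stood at 108.6 ± 7.4 CPM and with S94A-YAP1-MAML2 at 60.2 ± 2.45 CPM. MAML2 (chromosome 11, 95976598 to 96343180) stood at 3.36 ± 0.236 CPM with GFP, 3.08 ± 0.172 CPM with wtYAP1, 361.7 ± 12 CPM with S94A-YAP1-MAML2 and 2050 ± 245 CPM with YAP1-MAML2. Its level was 610-fold above GFP with YAP1-MAML2 and 108-fold above GFP with the S94A form, so the fusions differed 5.67-fold from each other. Each of these differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, except MAML2 between wtYAP1 and GFP with an exact p of 0.3. The counts do not separate plasmid transcripts from the cells' own. With the fusions YAP1 rose far less than MAML2 although 1 transcript carries parts of both, and whether all reads of the YAP1 part were counted is not known, so the YAP1 levels in the fusion libraries are uncertain.

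**Figure D1:**
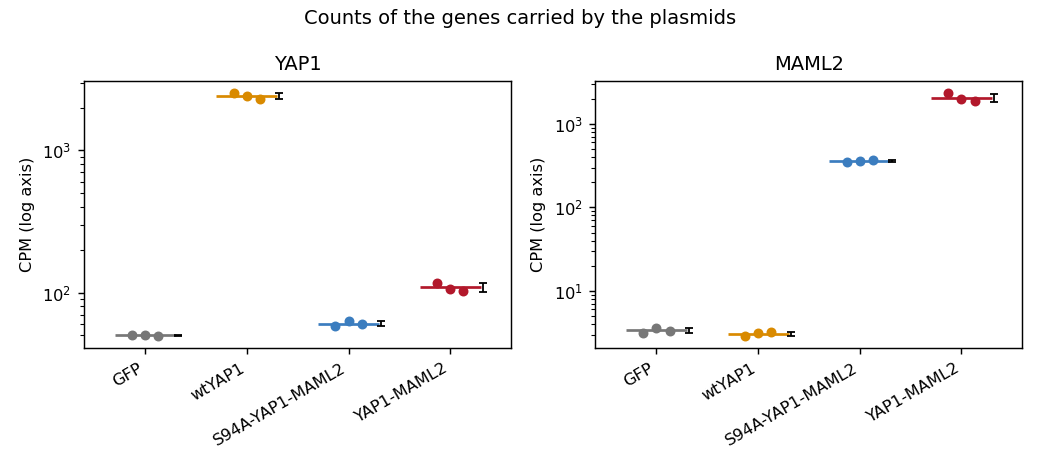
CPM of YAP1 and MAML2 on log axes in each library (points), with the group mean (line) and SD (bar, n = 3), for the 4 plasmids. MAML2 averaged 361.7 CPM with S94A-YAP1-MAML2 and 2050 CPM with YAP1-MAML2, and YAP1 averaged 2423 CPM with wtYAP1.

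The comparison of YAP1-MAML2 with GFP asks what the fusion does to the cells' transcripts. Of the 6 largest rises among genes with an average log2 CPM of at least 1, plasmid genes left out, 5 were in the list of YAP/TAZ-TEAD targets. CCN2 (connective tissue growth factor, chromosome 6, 131948176 to 131951373) rose 190-fold, from 1.49 ± 0.288 to 278.7 ± 10.4 CPM (SD, n = 3; log2 fold change 7.57 ± 0.07, edgeR adjusted p = 2.48e-49). ANKRD1, a nuclear ankyrin repeat protein (chromosome 10, 90912096 to 90921276), rose 72.4-fold from 1.547 ± 0.464 to 108.4 ± 3.76 CPM (6.18 ± 0.10, adjusted p = 6.96e-31). CCN1, a secreted matrix protein (chromosome 1, 85580761 to 85583962), rose from 14.19 ± 0.105 to 283.2 ± 1.59 CPM (4.32 ± 0.05, adjusted p = 4.78e-46). SALL4, a zinc finger factor of early development (chromosome 20, 51782331 to 51802520), rose by 2.65 ± 0.15 on the log2 scale (adjusted p = 5.03e-18). AMOTL2, which binds and restrains YAP1 (chromosome 3, 134355874 to 134375479), rose by 2.17 ± 0.05 (adjusted p = 3.28e-32), and the kinase NUAK2 rose 2.65-fold (adjusted p = 6.85e-08). The largest falls at that expression, among genes with a symbol, were smaller. INHBA, a subunit of activin, was 2.01-fold lower (adjusted p = 0.000119), and OSTN, C11orf96, PTGS2, RHEBL1 and GEM fell by 0.66 to 0.80 on the log2 scale with adjusted p from 1.24e-07 (GEM) to 0.028 (C11orf96). The call of RHEBL1 was lost without YAP1-MAML2 replicate 1 (adjusted p = 0.0694). That of C11orf96 was lost without YAP1-MAML2 replicate 1 (0.11), 2 (0.0724) or 3 (0.108).

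**Figure D2:**
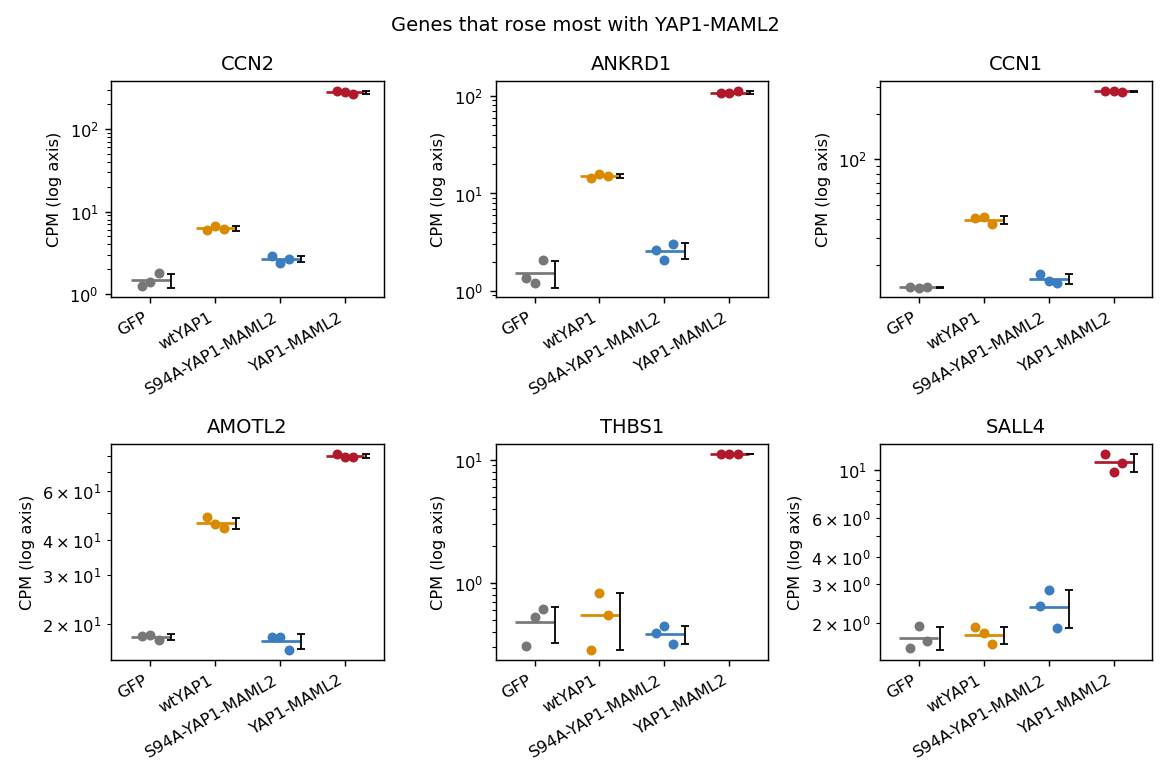
CPM of CCN2, ANKRD1, CCN1, AMOTL2, THBS1 and SALL4 on log axes in each library (points), with the group mean (line) and SD (bar, n = 3), for the 4 plasmids. CCN2 averaged 278.7 CPM with YAP1-MAML2, 6.256 CPM with wtYAP1, 2.66 CPM with S94A-YAP1-MAML2 and 1.49 CPM with GFP.

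Of the 22 YAP/TAZ-TEAD targets, 9 rose and 0 fell by edgeR over all 17457 genes, where 3666 genes had an unadjusted p under 0.05, and 12 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.47e-206, and adjusted p = 7.85e-08 with an estimated correlation). The Hippo kinase LATS2, itself a YAP1 target, was among them (0.42 ± 0.07, adjusted p = 0.000142). Among 16 extracellular matrix genes, THBS1, COL12A1 and COL4A2 rose and FN1 fell, by edgeR and adjusted over the list alone, and the list passed camera (adjusted p = 0.00406, and adjusted p = 0.328 with an estimated correlation). THBS1, a matrix glycoprotein, went from 0.4814 ± 0.157 to 11.16 ± 0.0736 CPM (4.55 ± 0.21, adjusted p = 1.77e-20), while FN1, fibronectin, fell by 0.30 on the log2 scale (adjusted p = 8.53e-05). COL4A2 rose by 0.13 (adjusted p = 0.0207), a call lost without GFP replicate 1 (0.0718), GFP replicate 3 (0.115), YAP1-MAML2 replicate 1 (0.122) or YAP1-MAML2 replicate 2 (0.0555), and with the GC and length trend removed, an alternative added after seeing the data (0.0847). The matrix list was lost with no low-count filter (0.116). Of 15 p53 targets 4 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0198, and adjusted p = 0.328 with an estimated correlation). The camera call of this list was lost without GFP replicate 1 (adjusted p = 0.115). PHLDA3, an inhibitor of AKT, rose by 0.56 (adjusted p = 3.36e-07), while CDKN1A, the cell cycle inhibitor p21, was lower by a log2 fold change of -0.14 (adjusted p = 0.0418). The CDKN1A call was lost without GFP replicate 2 (0.085) or 3 (0.177) and without YAP1-MAML2 replicate 1 (0.142), 2 (0.1) or 3 (0.0788), with limma-voom (0.0642), and with DESeq2 with no independent filtering, an alternative added after seeing the data (0.11). Of 10 TGF-beta and BMP response genes 3 rose, among them ID3 and BMP4, and 5 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0358, and adjusted p = 0.328 with an estimated correlation). That call was lost without GFP replicate 1 (0.103), GFP replicate 3 (0.146) or YAP1-MAML2 replicate 1 (0.107), with the stricter filter (0.0642), in a fit of the 2 groups only (0.0602) and with the GC and length trend removed (0.0717). Of 13 mitochondrially encoded mRNAs 6 rose, over all genes and adjusted over the list alone (camera adjusted p = 1.78e-10, and adjusted p = 0.258 with an estimated correlation). Among them was MT-ND4, a complex I subunit, at 7224 ± 363 against 5849 ± 227 CPM (adjusted p = 0.000136). The mitochondrial genome has near copies in the nuclear genome, so these counts are uncertain. The mitochondrial share of counts was above 3.2% only in the 6 fusion libraries. That share is a sum that includes these same genes, so it is not a separate observation.

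The other lists did not pass camera for YAP1-MAML2 against GFP. Of 26 Hippo and TEAD components, AJUBA (1.00 ± 0.06, adjusted p = 1.71e-17) and WWC2 rose and 1 fell, or 4 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.384, median log2 fold change -0.003, mean 0.037, test upward). Among 11 NOTCH targets, HEY1 fell by 0.26 on the log2 scale (adjusted p = 5.11e-05), while HES1 (-0.07, adjusted p = 0.719) and NRARP (-0.08, adjusted p = 0.506) were not called (camera adjusted p = 0.646; median 0.015 and mean 0.042, test downward). PTGS2 was the 1 call among 15 CREB targets (camera adjusted p = 0.347). IER3 and DUSP6 rose among 16 AP-1 and immediate early genes (camera adjusted p = 0.925; median -0.052, mean 0.001, test downward), where DUSP6 is a phosphatase of ERK kinases. Its call was lost without GFP replicate 1 (0.0803), GFP replicate 2 (0.133), YAP1-MAML2 replicate 2 (0.0523) or YAP1-MAML2 replicate 3 (0.0995), and with DESeq2 with no independent filtering (0.0561). FOS was not called (-0.26, adjusted p = 0.125), but was called lower under 1 of 17 alternatives, the leaving out of 1 library. ACTA2 and FLNA rose among 11 SRF/MRTF genes (camera adjusted p = 0.165), and MCM5, CCNE1 and MCM2 among 21 DNA replication genes (0.232), with MCM2 lost without GFP replicate 1 (0.0573), YAP1-MAML2 replicate 1 (0.0692) or YAP1-MAML2 replicate 2 (0.058). TOP2A was lower among 20 mitosis genes (0.646), a call lost without GFP replicate 3 (0.112) or YAP1-MAML2 replicate 1 (0.167). Of 17 unfolded protein and ATF4 response genes 4 fell, or 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0848). ADM, a vasodilator peptide, rose among 15 hypoxia and glycolysis genes (camera adjusted p = 0.948; median -0.007, mean 0.03, test upward). OAS3 rose among 15 interferon genes (0.948) and MVD among 17 cholesterol synthesis genes (0.646). OAS3 lost its call without GFP replicate 1 (0.0702) or YAP1-MAML2 replicate 3 (0.0957), and MVD without GFP replicate 3 (0.154), YAP1-MAML2 replicate 2 (0.108) or YAP1-MAML2 replicate 3 (0.0794). With the GC and length trend removed, an alternative added after seeing the data, TOP2A was at -0.029 (0.576), MCM2 at 0.057 (0.164) and MVD at 0.093 (0.207), and none of them was called. NRARP was called lower with that trend removed (-0.187, adjusted p = 0.0399).

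By edgeR, 0 members were called among 11 WNT targets (camera adjusted p = 0.948; median 0.054, mean 0.095, test downward), 7 NF-kappaB targets (0.646), 10 heat shock genes (0.768; median -0.011, mean 0.037, test upward), 8 histone genes (0.948) and 8 neuronal markers (0.646; median -0.066, mean 0.072, test downward), in a comparison with 3666 genes at an unadjusted p under 0.05 and 698 and 620 calls by DESeq2. The histone genes have near-identical copies and their counts are uncertain. Too few members for a test were expressed of the markers of fibroblasts (4), blood cells (2) and endothelium (1), with 0 called by edgeR. Of 4 keratin epithelium markers, the simple epithelial keratins KRT8 and KRT18, which HEK293 cells also express, rose by 1.26 ± 0.04 (adjusted p = 9.93e-26) and 0.79 ± 0.04 (adjusted p = 1.85e-20).

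In total, edgeR called 641 genes higher and 596 lower with YAP1-MAML2 than with GFP, of which 54 and 14 changed at least 2-fold and 90.2% of all calls changed under 1.5-fold. With library totals in place of TMM the split was 550 higher and 771 lower. The counts were 396 and 354 without GFP replicate 1, 517 and 390 without GFP replicate 2, 406 and 350 without GFP replicate 3, 353 and 242 without YAP1-MAML2 replicate 1, 379 and 316 without replicate 2 and 444 and 361 without replicate 3. Fold changes also went with the GC content of the transcript (Spearman rho 0.49 across 11588 genes, which are not independent replicates), and with that trend removed, an alternative added after seeing the data, 408 genes were higher and 290 lower. With DESeq2 with no independent filtering, also added after seeing the data, 465 were higher and 362 lower.

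**Figure D3:**
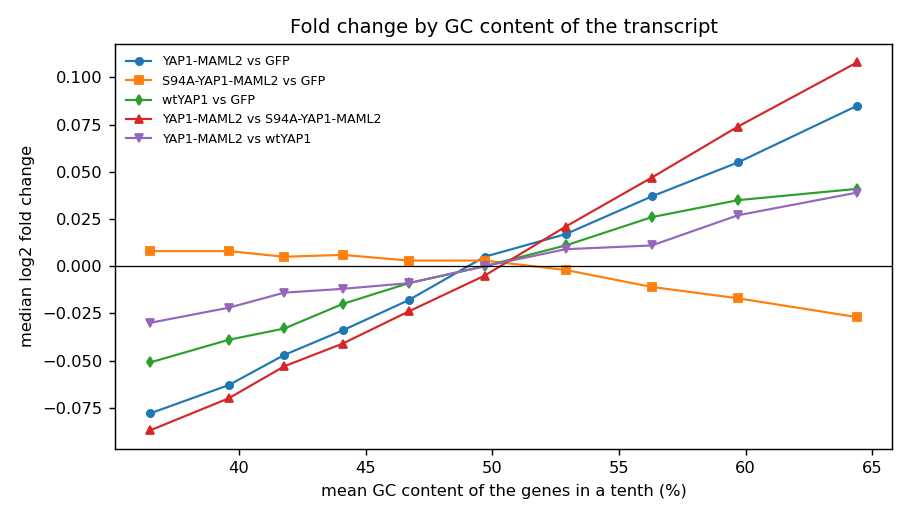
Median log2 fold change of genes in 10 groups by GC content of the longest transcript (percent, horizontal axis), 1 line per comparison. For YAP1-MAML2 against GFP the median went from -0.078 in the group with a mean GC content of 36.5% to 0.085 in the group with 64.4%.

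The comparison of S94A-YAP1-MAML2 with GFP asks what the fusion with the S94A change does to the cells' transcripts. MAML2 counts were 5.67-fold lower with this form than with YAP1-MAML2. Weaker effects than those of YAP1-MAML2 therefore cannot be put down to the S94A change alone. CCN2 stood at 2.66 ± 0.237 CPM against 1.49 ± 0.288 CPM with GFP (log2 fold change 0.86 ± 0.12, n = 3 per group, edgeR adjusted p = 6.29e-05) and ANKRD1 at 2.591 ± 0.48 against 1.547 ± 0.464 CPM (0.79 ± 0.15, adjusted p = 0.0184). CCN1 (0.18 ± 0.06, adjusted p = 0.312), AMOTL2 (-0.05 ± 0.06, adjusted p = 0.894) and LATS2 (-0.10 ± 0.07, adjusted p = 0.782) were not called. Nor were HES1 (adjusted p = 0.949), HEY1 (0.894), NRARP (0.893) and FOS (0.756). Other rises were in MT-ND4L (0.35 ± 0.04, adjusted p = 0.00207), MT-ND4 (0.34 ± 0.04, adjusted p = 0.000295), MT-ND1 (0.31 ± 0.04, adjusted p = 8.5e-05) and TTC30A, a protein of the ciliary transport machinery (0.41 ± 0.09, adjusted p = 0.0411). PPP1R15A, the stress-induced phosphatase subunit GADD34 (chromosome 19, 48872392 to 48876057), went from 58.02 ± 1.3 to 46.25 ± 2.48 CPM (-0.33 ± 0.05, adjusted p = 2.19e-05). ZCCHC12 fell by 0.32 (adjusted p = 0.000295), SLC3A2, a chain of amino acid transporters, fell by 0.23 (adjusted p = 4.74e-06), and the mitochondrial helicase TWNK and ZFTA were each 1.16-fold lower (adjusted p = 0.00587 and 0.0411).

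Of the 22 YAP/TAZ-TEAD targets, 2 rose, and 3 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0968). Of the 13 mitochondrially encoded mRNAs 4 rose, and 10 adjusted over the list alone (camera adjusted p = 3.11e-58, and adjusted p = 0.0032 with an estimated correlation). The mitochondrial share of counts, a sum that includes these same genes, was at least 3.24% in each fusion library. MT-ND4 and MT-ND4L overlap on the mitochondrial genome, so their counts are not independent, and near copies in the nuclear genome make them uncertain. A further 5 lists passed camera with 0 members called by edgeR over all genes or adjusted over the list alone, in a comparison with 1359 genes at an unadjusted p under 0.05 and 27 calls by DESeq2 and 19 by limma-voom. AP-1 and immediate early genes were lower (adjusted p = 0.000293, and adjusted p = 0.578 with an estimated correlation), with JUN at -0.05 (adjusted p = 0.963). Their call was lost without GFP replicate 1 (0.0552) or S94A-YAP1-MAML2 replicate 3 (0.208). Unfolded protein and ATF4 response genes were lower (adjusted p = 0.00992, and adjusted p = 0.578 with an estimated correlation), a call lost without GFP replicate 1 (0.193), S94A-YAP1-MAML2 replicate 2 (0.0599) or replicate 3 (0.174). Extracellular matrix genes were higher (adjusted p = 0.0352, and adjusted p = 0.578 with an estimated correlation), which was lost without GFP replicate 2 (0.126), GFP replicate 3 (0.161), S94A-YAP1-MAML2 replicate 1 (0.136) or replicate 2 (0.631), with library totals alone (0.0562) and with the GC and length trend removed, an alternative added after seeing the data (0.0873). Cholesterol synthesis genes were higher (adjusted p = 0.0255, and adjusted p = 0.578 with an estimated correlation), which was lost without GFP replicate 1 (0.226), GFP replicate 3 (0.0885), S94A-YAP1-MAML2 replicate 1 (0.514) or replicate 2 (0.0784), and with library totals alone (0.0587). Hypoxia and glycolysis genes were higher (adjusted p = 0.0255, and adjusted p = 0.791 with an estimated correlation), which was lost without GFP replicate 2 (0.0623), GFP replicate 3 (0.0885) or S94A-YAP1-MAML2 replicate 2 (0.0901), while without S94A-YAP1-MAML2 replicate 1 (0.782) its direction turned. With fry these 5 lists were not called (adjusted p = 0.435 for AP-1, matrix and unfolded protein genes, 0.493 for cholesterol synthesis and 0.771 for hypoxia and glycolysis).

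In total, edgeR called 11 genes higher, YAP1 and MAML2 included, and 6 lower, among them DNAH17, an axonemal dynein chain, which fell by 1.69 ± 0.20 on the log2 scale (adjusted p = 5.3e-07). Without GFP replicate 1 there were 25 higher, without GFP replicate 2 there were 6 higher, and without S94A-YAP1-MAML2 replicate 3 there were 24 higher and 16 lower. DESeq2 called 20 higher and 7 lower but gave no adjusted p to CCN2, ANKRD1, TTC30A, PPP1R15A, ZCCHC12, TWNK and ZFTA. It shared 7 of the 11 and 1 of the 6 edgeR calls. With no independent filtering, an alternative added after seeing the data, it called 12 higher and 6 lower, these 7 genes among them, and shared 10 and 6. There were 27 higher and 12 lower with no low-count filter, and 7 higher in a fit of the 2 groups only. CCN2 was lost with limma-voom (adjusted p = 0.122) and in a fit of these 2 groups only (0.123). ANKRD1 was lost with limma-voom (0.242), in a fit of the 2 groups only (0.398), and without GFP replicate 1 (0.0907), GFP replicate 2 (0.297), S94A-YAP1-MAML2 replicate 1 (0.0771) or replicate 3 (0.0594). YAP1 was lost without GFP replicate 2 (0.065), GFP replicate 3 (0.0863) or S94A-YAP1-MAML2 replicate 3 (0.117), with limma-voom (0.0839) and with the GC and length trend removed, an alternative added after seeing the data (0.174). MT-ND4 (0.0542) and MT-ND4L (0.0575) were lost without S94A-YAP1-MAML2 replicate 3. TWNK was lost without S94A-YAP1-MAML2 replicate 2 (0.177). TTC30A was lost without GFP replicate 1 (0.177), 2 (0.065) or 3 (0.146) and without S94A-YAP1-MAML2 replicate 1 (0.0954), 2 (0.102) or 3 (0.0684), with library totals alone (0.0609) and in a fit of the 2 groups only (0.123). ZFTA was lost without GFP replicate 1 (0.125), 2 (0.167) or 3 (0.126) and without S94A-YAP1-MAML2 replicate 1 (0.091) or 2 (0.47), with limma-voom (0.0578), in a fit of the 2 groups only (0.122) and with the GC and length trend removed (0.11).

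The comparison of wtYAP1 with GFP shows what more YAP1 does on its own. ANKRD1 rose from 1.547 ± 0.464 to 15.05 ± 0.696 CPM (log2 fold change 3.33 ± 0.11, n = 3 per group, edgeR adjusted p = 9.8e-21), CCN2 to 6.256 ± 0.38 CPM (2.09 ± 0.10, adjusted p = 6.51e-20), CCN1 to 39.81 ± 2.44 CPM (1.49 ± 0.05, adjusted p = 4.4e-26) and AMOTL2 to 46.04 ± 2.15 CPM (1.36 ± 0.05, adjusted p = 7.62e-24). The small heat shock protein HSPB8 rose 3.04-fold (adjusted p = 1.67e-08) and the dehydrogenase DHRS2 by 1.01 ± 0.12 (adjusted p = 1.8e-07). LATS2 (0.11, adjusted p = 0.582), HES1 (-0.02, adjusted p = 0.952), HEY1 (-0.10, adjusted p = 0.33), NRARP (-0.05, adjusted p = 0.797) and FOS (adjusted p = 0.678) were not called. Among genes with an average log2 CPM of at least 1, the largest falls lay between 0.24 and 0.27 on the log2 scale, in ERO1B, PTAR1, ACAP2, MTND4P12, SPIN4 and SESTD1, with PTAR1 at adjusted p = 0.000817. MTND4P12 is a pseudogene copy of MT-ND4, so the counts of both are uncertain. The other calls were lost when 1 library was left out. ERO1B was lost without GFP replicate 2 (0.116), wtYAP1 replicate 1 (0.0884) or 2 (0.0566), and ACAP2 without wtYAP1 replicate 3 (0.0819). MTND4P12 was lost without GFP replicate 2 (0.143) or 3 (0.123) and wtYAP1 replicate 1 (0.11) or 3 (0.188), with limma-voom (0.0607) and with DESeq2 with no independent filtering, an alternative added after seeing the data (0.0588). SESTD1 was lost without GFP replicate 1 (0.154) or 3 (0.0601) and wtYAP1 replicate 2 (0.142) or 3 (0.213), and with the GC and length trend removed, an alternative added after seeing the data, where it was at -0.157 (0.201). SPIN4 was lost without GFP replicate 1 (0.162), 2 (0.159) or 3 (0.0724) and wtYAP1 replicate 1 (0.0814), 2 (0.355) or 3 (0.11), with limma-voom (0.0752), DESeq2 size factors (0.051) or library totals alone (0.0521), DESeq2 with no independent filtering (0.114), and with the GC and length trend removed (0.131).

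Of the 22 YAP/TAZ-TEAD targets, 5 rose with wtYAP1, and 7 adjusted over the list alone (camera adjusted p = 1.61e-65, and adjusted p = 8.96e-06 with an estimated correlation). DDB2 and PHLDA3 rose among 15 p53 targets, and 4 rose adjusted over the list alone (camera adjusted p = 0.000351, and adjusted p = 0.0721 with an estimated correlation). ACTA2 (0.52 ± 0.08, adjusted p = 0.000107) and FLNA rose among 11 SRF/MRTF genes, also adjusted over the list alone (camera adjusted p = 0.00491, adjusted p = 0.261 with an estimated correlation, and adjusted p = 0.0712 with fry). FLNA was lost without GFP replicate 3 (0.111), wtYAP1 replicate 1 (0.0745) or 3 (0.155). H1-2 and H2BC12 rose among 8 histone genes, also adjusted over the list alone (camera adjusted p = 0.00262, and adjusted p = 0.0721 with an estimated correlation), 1 of them, H2BC12, with near-identical copies. H1-2 was lost without GFP replicate 2 (0.0812), GFP replicate 3 (0.0627) or wtYAP1 replicate 1 (0.139), and H2BC12 without GFP replicate 1 (0.0811), wtYAP1 replicate 2 (0.0518) or 3 (0.0558). Both genes were lost with the GC and length trend removed, an alternative added after seeing the data (0.0631). ID3 rose among 10 TGF-beta and BMP response genes, also adjusted over the list alone (camera adjusted p = 0.0496, and adjusted p = 0.433 with an estimated correlation). That list was lost without GFP replicate 1 (0.164), GFP replicate 3 (0.328), wtYAP1 replicate 1 (0.0734), 2 (0.0548) or 3 (0.084), with no low-count filter (0.0658), with the stricter filter (0.0648), with fry (0.187) and with the GC and length trend removed (0.103).

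Other lists were lower with wtYAP1. CENPF, a kinetochore protein, fell among 20 mitosis genes, of which 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0496, and adjusted p = 0.504 with an estimated correlation), and the list was lost without GFP replicate 3 (0.401), wtYAP1 replicate 2 (0.0827) or 3 (0.143), with no low-count filter (0.0782), with the stricter filter (0.0741) and with fry (0.192). The extracellular matrix list was lower by camera (adjusted p = 0.0321, and adjusted p = 0.498 with an estimated correlation) although its 1 call, COL12A1, was a rise, and 1 rose and 4 fell adjusted over the list alone. The list was lost without GFP replicate 1 (0.164) or wtYAP1 replicate 1 (0.102), with the stricter filter (0.0523), with fry (0.217) and with the GC and length trend removed, an alternative added after seeing the data (0.0745). COL12A1 was lost without GFP replicate 2 (0.134), wtYAP1 replicate 1 (0.0525) or 3 (0.116). By edgeR, 0 members were called among 15 hypoxia and glycolysis genes and 13 mitochondrially encoded mRNAs, over all genes or adjusted over the list alone, in a comparison with 2058 genes at an unadjusted p under 0.05 and 137 and 78 calls by DESeq2. Both lists were lower by camera, the first with adjusted p = 0.0199 (adjusted p = 0.718 with an estimated correlation) and the second with adjusted p = 0.000409 (adjusted p = 0.485 with an estimated correlation). The first was lost without wtYAP1 replicate 3 (0.147), with no low-count filter (0.0684) and with fry (0.6), and the second, whose counts are uncertain for their nuclear copies, with fry (0.262). In total, edgeR called 98 genes higher, 14 of them at least 2-fold, and 34 lower. Without wtYAP1 replicate 1 there were 53 higher and 24 lower, without wtYAP1 replicate 2 there were 66 and 5, without wtYAP1 replicate 3 there were 49 and 5, without GFP replicate 1 there were 70 and 18, and without GFP replicate 2 there were 71 and 14. A fit of the 2 groups only gave 201 and 115, no low-count filter 145 and 76, DESeq2 137 and 78, DESeq2 with no independent filtering, an alternative added after seeing the data, 88 and 22, and removal of the GC and length trend 80 and 14.

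The comparison of YAP1-MAML2 with S94A-YAP1-MAML2 sets the fusion against its form with the S94A change, at MAML2 counts that also differed 5.67-fold. CCN2 was 105-fold higher with YAP1-MAML2 (log2 fold change 6.71 ± 0.06, n = 3 per group, edgeR adjusted p = 1.01e-48). ANKRD1 was higher by 5.39 ± 0.09 (adjusted p = 3.26e-30), CCN1 by 4.14 ± 0.05 (adjusted p = 1.44e-45), AMOTL2 by 2.22 ± 0.05 (adjusted p = 1.44e-32), SALL4 by 2.18 ± 0.14 (adjusted p = 9.23e-16), and the membrane repair protein MYOF stood at 5.583 against 2.199 CPM (adjusted p = 1.53e-08). THBS1 stood at 11.16 ± 0.0736 against 0.3836 ± 0.064 CPM (4.85 ± 0.22, adjusted p = 5.41e-21), and LATS2 was higher by 0.53 ± 0.07 (adjusted p = 2.8e-06). HEY1 was lower by a log2 fold change of -0.22 ± 0.04 (adjusted p = 0.000385), while HES1 (-0.03, adjusted p = 0.899), NRARP (-0.02, adjusted p = 0.876) and FOS (-0.10, adjusted p = 0.612) were not called. OSTN, a secreted peptide of muscle and bone, fell (-0.69 ± 0.13, adjusted p = 0.000351). INHBA, ZNF713, NGFR, ANKRD36C and PTX3 were lower by 0.54 to 0.65 on the log2 scale with adjusted p of 0.0113 to 0.0494, and ANKRD36C has near copies, so its counts are uncertain. INHBA was lost without S94A-YAP1-MAML2 replicate 2 (0.0957) or YAP1-MAML2 replicate 2 (0.118), PTX3 without S94A-YAP1-MAML2 replicate 2 (0.076) or YAP1-MAML2 replicate 1 (0.117), and ANKRD36C without S94A-YAP1-MAML2 replicate 2 (0.125) or YAP1-MAML2 replicate 1 (0.0779). NGFR was lost without S94A-YAP1-MAML2 replicate 1 (0.0998) or 3 (0.143) and YAP1-MAML2 replicate 1 (0.0805), 2 (0.0679) or 3 (0.108). ZNF713 was lost without S94A-YAP1-MAML2 replicate 2 (0.121) or 3 (0.235) and YAP1-MAML2 replicate 1 (0.125), 2 (0.14) or 3 (0.0842). NGFR (0.075) and ZNF713 (0.104) were lost with limma-voom, and ZNF713 also in a fit of the 2 groups only (0.0809) and with library totals (0.0503), DESeq2 size factors (0.0514), no low-count filter (0.0595) or the stricter filter (0.0506). With the GC and length trend removed, an alternative added after seeing the data, INHBA (0.0507), ANKRD36C (0.0533) and ZNF713 (0.113) were lost. NGFR (0.0908) and ZNF713 (0.135) were lost with DESeq2 with no independent filtering, also added after seeing the data.

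Of the 22 YAP/TAZ-TEAD targets, 8 rose and DOCK5 fell, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.21e-190, and adjusted p = 1.19e-07 with an estimated correlation). DOCK5 was lost without YAP1-MAML2 replicate 1 (0.0792) and with the GC and length trend removed, where it was at -0.164 (0.159). Of 10 TGF-beta and BMP response genes 3 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0353, and adjusted p = 0.365 with an estimated correlation), and of 15 p53 targets 5 rose, also adjusted over the list alone (camera adjusted p = 0.0353, and adjusted p = 0.365 with an estimated correlation). Both lists were lost without YAP1-MAML2 replicate 1 (0.0501), and p53 targets also without S94A-YAP1-MAML2 replicate 3 (0.0563). Both were lost, too, with the stricter filter (0.0613) and with the GC and length trend removed, an alternative added after seeing the data (0.0672). In total, edgeR called 880 genes higher and 753 lower, 49 and 14 of them at least 2-fold, and 92.8% of calls changed under 1.5-fold. Without YAP1-MAML2 replicate 1 there were 439 higher and 269 lower, without S94A-YAP1-MAML2 replicate 2 there were 432 lower, without S94A-YAP1-MAML2 replicate 3 there were 458 lower and without YAP1-MAML2 replicate 2 there were 495 lower. With the GC and length trend removed there were 374 higher and 177 lower, in a fit of the 2 groups only 711 and 469, and with DESeq2 with no independent filtering 715 and 448. Fold changes went with GC content here too (Spearman rho 0.56 across 11588 genes, which are not independent replicates). Of the 880 and 753 calls, 276 and 119 were kept in the same direction with that trend removed.

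The comparison of YAP1-MAML2 with wtYAP1 asks how the fusion differs from the protein it derives from, across the ranges of sample numbers given above. CCN2 was 44.6-fold higher with the fusion (log2 fold change 5.48 ± 0.06, n = 3 per group, edgeR adjusted p = 1.94e-47). ANKRD1 was higher by 2.85 ± 0.07 (adjusted p = 3.84e-25), CCN1 by 2.83 ± 0.04 (adjusted p = 1.26e-40), SALL4 by 2.61 ± 0.15 (adjusted p = 5.86e-18) and AMOTL2 by 0.80 ± 0.05 (adjusted p = 3.23e-17). KRT8 was higher by 1.15 ± 0.04 (adjusted p = 2.76e-24) and the homeobox gene HOXC12 by 1.13 ± 0.15 (adjusted p = 1.17e-06). HSPB8 was 2.08-fold lower (adjusted p = 5.99e-05), DHRS2 lower by a log2 fold change of -1.04 ± 0.12 (adjusted p = 6.26e-08) and PPP1R15A by -0.50 ± 0.04 (adjusted p = 3.12e-11). The histone genes H2BC11 (-0.87, adjusted p = 0.000717; uncertain, with near-identical copies) and H1-2 (-0.58, adjusted p = 0.000135) were also lower. So was HES7 (-0.53, adjusted p = 0.0393), a call lost without wtYAP1 replicate 1 (0.0897) or 2 (0.269) and YAP1-MAML2 replicate 1 (0.0976), 2 (0.202) or 3 (0.0747), with limma-voom (0.0912) and with DESeq2 with no independent filtering, an alternative added after seeing the data (0.0866). HES1 (-0.05, adjusted p = 0.885), NRARP (-0.03, adjusted p = 0.913) and FOS (-0.13, adjusted p = 0.649) were not called. LATS2 was higher (0.31, adjusted p = 0.0115) and HEY1 lower (-0.17, adjusted p = 0.0273). LATS2 was lost without wtYAP1 replicate 1 (0.0688) or 3 (0.0756) and YAP1-MAML2 replicate 2 (0.0542) or 3 (0.0943). HEY1 was lost without wtYAP1 replicate 1 (0.186), 2 (0.0681) or 3 (0.0756) and YAP1-MAML2 replicate 1 (0.241) or 2 (0.0531), and with DESeq2 with no independent filtering (0.0569).

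Of the 22 YAP/TAZ-TEAD targets, 8 rose, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.59e-159, and adjusted p = 3.87e-07 with an estimated correlation). THBS1 (4.36 ± 0.20, adjusted p = 2.48e-20), COL12A1 and FBN1 rose among 16 extracellular matrix genes, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.35e-09, and adjusted p = 0.0379 with an estimated correlation). FBN1 was lost without wtYAP1 replicate 1 (0.129), 2 (0.0986) or 3 (0.182) and YAP1-MAML2 replicate 1 (0.178) or 2 (0.161), with library totals alone (0.0547), with limma-voom (0.0678) and with DESeq2 with no independent filtering, an alternative added after seeing the data (0.0798). Of 13 mitochondrially encoded mRNAs 6 rose, and 9 adjusted over the list alone (camera adjusted p = 1.35e-29, and adjusted p = 0.0159 with an estimated correlation). The mitochondrial share of counts, a sum that includes these same genes, was at least 3.24% in the fusion libraries. The mitochondrial genome has near copies in the nuclear genome, so these counts are uncertain. ADM was the 1 call among 15 hypoxia and glycolysis genes (camera adjusted p = 0.0449, and adjusted p = 0.881 with an estimated correlation), a list lost without wtYAP1 replicate 3 (0.188), YAP1-MAML2 replicate 2 (0.695) or 3 (0.31), with library totals alone (0.0562), no low-count filter (0.0645), the stricter filter (0.0918) or fry (0.645), and with the GC and length trend removed, an alternative added after seeing the data (0.0644). H1-2 was the 1 call among 8 histone genes, of which 2 fell adjusted over the list alone (camera adjusted p = 0.0165, and adjusted p = 0.122 with an estimated correlation), and the list was lost without YAP1-MAML2 replicate 3 (0.0717). In total, edgeR called 138 genes higher and 97 lower, 29 and 11 of them at least 2-fold. Without wtYAP1 replicate 1 there were 95 higher and 53 lower, without wtYAP1 replicate 2 there were 77 and 33, without wtYAP1 replicate 3 there were 69 and 37, without YAP1-MAML2 replicate 2 there were 76 and 43 and without YAP1-MAML2 replicate 3 there were 79 and 40. A fit of the 2 groups only gave 290 and 192, and removal of the GC and length trend 183 and 158.

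The calls of different plasmids against GFP were also compared. YAP1-MAML2 and wtYAP1 had 64 higher genes and 17 lower genes in common, with 3 called in opposite directions, where independent lists of the same sizes would share 3.6 and 1.16. YAP1-MAML2 and S94A-YAP1-MAML2 shared 8 higher and 4 lower genes (0.404 and 0.205 for independent lists), and wtYAP1 and S94A-YAP1-MAML2 shared 3 higher and 0 lower genes by edgeR, with 2 in opposite directions (0.0618 and 0.0117 for independent lists). These counts include the plasmid genes. The 8 are YAP1, MAML2, 4 mitochondrially encoded mRNAs, CCN2 and ANKRD1, the 3 are YAP1, CCN2 and ANKRD1, and YAP1 is also among the 64. A simulation added after seeing the data gave the first group its called fold changes, put those of the second group on random genes of similar expression, and set both against the same simulated GFP libraries. Its edgeR calls in common, higher and lower, averaged 3.9 and 1.4 over 20 simulations for YAP1-MAML2 and wtYAP1, 0.55 and 0.25 for YAP1-MAML2 and S94A-YAP1-MAML2, and 0.15 and 0.05 for wtYAP1 and S94A-YAP1-MAML2. Without the plasmid genes the real counts were 63 and 17, 6 and 4, and 2 and 0. Across 12683 genes the covariance of log2 fold changes was 0.0116 for YAP1-MAML2 with wtYAP1, 0.00541 for YAP1-MAML2 with S94A-YAP1-MAML2 and 0.00148 for wtYAP1 with S94A-YAP1-MAML2, beside 0.00332 in simulations of unchanged groups. The 3 GFP libraries are too few to divide, so part of the shared calls may come from the shared controls. The simulations held no trend on GC content or length common to 2 groups. Fold changes against GFP went with GC content for both YAP1-MAML2 (Spearman rho 0.49) and wtYAP1 (0.37). Part of their shared calls may therefore come with that trend, which the simulations did not test. Of the 52 genes other than YAP1 and MAML2 that rose at least 2-fold with YAP1-MAML2, 10 also rose with wtYAP1, 2 rose with S94A-YAP1-MAML2, and 35 were higher with YAP1-MAML2 than with S94A-YAP1-MAML2.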

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

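Of the calls of named genes, counted once per comparison, DESeq2 kept 161, lost 1 and gave no adjusted p for 13, 7 of them in S94A-YAP1-MAML2 vs GFP, limma-voom kept 159 and lost 16, fits of only the 2 groups compared kept 158 and lost 17, no low-count filter kept 169 and lost 6, and the stricter filter kept 174 and lost 1. Library totals alone kept 171 and lost 4, DESeq2 size factors kept 172 and lost 3, leaving out the plasmid genes kept all 166, and leaving out 1 library at a time kept 848 values and lost 202. The GC and length correction, chosen after seeing the data, kept 137 and lost 38, and DESeq2 with no independent filtering, also chosen then, kept 156 and lost 19. None of these reversed a call of a named gene, while log2 fold changes of some genes that were not called changed sign. The GC and length correction added 1 call of a named gene, and leaving out 1 library at a time added 1. The cause of a change below was not tested unless it follows from how the alternative is built, as with fewer libraries or a stricter threshold. Low counts limit all of these tests most where genes have few counts per library.

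The counts that moved by over 1.5 times are given as higher and lower. At an adjusted p under 0.01 they were 255 and 158 for YAP1-MAML2 vs GFP, 7 higher for S94A-YAP1-MAML2 vs GFP, 51 and 5 for wtYAP1 vs GFP, 428 and 250 for YAP1-MAML2 vs S94A-YAP1-MAML2, and 76 and 34 for YAP1-MAML2 vs wtYAP1. Of at least 2-fold they were, in the same order, 54 and 14, 1 and 1, 14 and 0, 49 and 14, and 29 and 11. The 0 stands for edgeR beside 2058 genes at an unadjusted p under 0.05, and DESeq2 called 78 and limma-voom 25 lower of any size. Fits of only the 2 groups compared gave 7 higher for S94A-YAP1-MAML2 vs GFP, 201 and 115 for wtYAP1 vs GFP, 469 lower for YAP1-MAML2 vs S94A-YAP1-MAML2, and 290 and 192 for YAP1-MAML2 vs wtYAP1. DESeq2 gave 20 higher for S94A-YAP1-MAML2 vs GFP and 78 lower for wtYAP1 vs GFP. With no low-count filter there were 27 and 12 for S94A-YAP1-MAML2 vs GFP and 76 lower for wtYAP1 vs GFP. With the GC and length trend removed there were 408 and 290 for YAP1-MAML2 vs GFP, 14 lower for wtYAP1 vs GFP, 374 and 177 for YAP1-MAML2 vs S94A-YAP1-MAML2, and 158 lower for YAP1-MAML2 vs wtYAP1. Main calls in the same direction made up 303 and 193, 9, 276 and 119, and 91 of these, in that order. DESeq2 with no independent filtering gave 362 lower for YAP1-MAML2 vs GFP, 22 lower for wtYAP1 vs GFP and 448 lower for YAP1-MAML2 vs S94A-YAP1-MAML2. Leaving out 1 library at a time gave 353 to 517 and 242 to 390 for YAP1-MAML2 vs GFP, 6 to 25 and 5 to 16 for S94A-YAP1-MAML2 vs GFP, 49 to 71 and 5 to 31 for wtYAP1 vs GFP, 439 to 943 and 269 to 849 for YAP1-MAML2 vs S94A-YAP1-MAML2, and 69 to 130 and 33 to 77 for YAP1-MAML2 vs wtYAP1.

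The number of gene lists past the threshold by camera was 5 for YAP1-MAML2 vs GFP, 6 for S94A-YAP1-MAML2 vs GFP, 9 for wtYAP1 vs GFP, 3 for YAP1-MAML2 vs S94A-YAP1-MAML2 and 5 for YAP1-MAML2 vs wtYAP1. With an estimated correlation it was 1, 1, 1, 1 and 3. With fry it was 1 for S94A-YAP1-MAML2 vs GFP, 4 for wtYAP1 vs GFP and 5 for YAP1-MAML2 vs S94A-YAP1-MAML2. The stricter filter gave 5 for wtYAP1 vs GFP, 1 for YAP1-MAML2 vs S94A-YAP1-MAML2 and 3 for YAP1-MAML2 vs wtYAP1, but in the first and last of these the histone list, which camera had called, had too few members left to be tested and so was not lost by a test. No low-count filter gave 9 and the GC and length correction 1 for YAP1-MAML2 vs S94A-YAP1-MAML2. Leaving out 1 library gave 3 to 6, 2 to 4, 6 to 9, 2 to 6 and 3 to 7 in the order above. The hypoxia and glycolysis list, S94A-YAP1-MAML2 vs GFP, turned to a median of -0.001 without S94A-YAP1-MAML2 replicate 1, and medians ranged from there to 0.123 (without S94A-YAP1-MAML2 replicate 3).

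Replicate numbers do not pair the libraries. Deviations from the group means of same-numbered libraries correlated at -0.074 to 0.062 over 18 pairs, and 4 of the 12 libraries correlated best with one of their own number. With the replicate block, edgeR called 678 higher and 594 lower for YAP1-MAML2 vs GFP, 12 and 6 for S94A-YAP1-MAML2 vs GFP, 99 and 37 for wtYAP1 vs GFP, 903 and 729 for YAP1-MAML2 vs S94A-YAP1-MAML2 and 157 and 101 for YAP1-MAML2 vs wtYAP1. Of the calls of named genes the replicate block kept 172 and ended 3, ZNF713 for YAP1-MAML2 vs S94A-YAP1-MAML2 among them (adjusted p = 0.0532). Then 5 lists passed camera for YAP1-MAML2 vs S94A-YAP1-MAML2 with the replicate block.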

Other observations

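The genes in this paragraph and the next were chosen after their values were seen. Several genes near silence with GFP were present with YAP1-MAML2. CPA4, a secreted carboxypeptidase, went from 0.01491 to 4.218 CPM (n = 3 per group, log2 fold change 7.97 ± 0.46, edgeR adjusted p = 1.18e-17). NPPB, the precursor of a cardiac natriuretic peptide, went from 0.006051 to 2.168 CPM (adjusted p = 5.39e-13) and stood at 0.5042 CPM with wtYAP1 (adjusted p = 1.6e-06). MYOCD, a coactivator of SRF in muscle, went from 0.05371 to 1.339 CPM (4.51 ± 0.60, adjusted p = 1.32e-06) and ALPK2, a kinase, from 0.03987 to 1.322 CPM (adjusted p = 3.2e-08). LIN28A, an RNA-binding protein of early development, averaged 1.302 CPM with YAP1-MAML2 (adjusted p = 2.77e-09) and had 0 counts in the 3 GFP libraries. Of the 52 genes at least 2-fold higher with YAP1-MAML2 than with GFP, plasmid genes left out, 20 had a GFP mean under 0.1 CPM.

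COL5A3, a fibrillar collagen chain, was near silence with GFP (0.051 CPM) and S94A-YAP1-MAML2 (0.02811 CPM), and stood at 2.066 CPM with wtYAP1 (adjusted p = 4.67e-11) and 1.547 CPM with YAP1-MAML2 (adjusted p = 5.75e-10). PPP1R15A rose with wtYAP1 (0.28 ± 0.04, adjusted p = 8.35e-05) and fell with S94A-YAP1-MAML2 (-0.33 ± 0.05, adjusted p = 2.19e-05) and YAP1-MAML2 (-0.22 ± 0.05, adjusted p = 0.00162). DNAH17 (chromosome 17, 78423697 to 78577394) stood at 2.867 CPM with GFP, 3.096 CPM with wtYAP1, 0.8834 CPM with S94A-YAP1-MAML2 and 0.4312 CPM with YAP1-MAML2 (-2.72 ± 0.22 against GFP, adjusted p = 1.95e-12).

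The predictions for regrouped libraries were written before their results were seen, and all other tests below were chosen only after the result was seen. The 6 libraries of each comparison were divided in all 10 ways into 3 and 3, and fits of the 2 groups alone were counted. These 10 are too few for any share under 0.05. Every grouping but the real one mixes the plasmids, so a real difference widens the spread within its groups and lowers its calls. Counts of those groupings therefore do not show what libraries without a difference would give. For YAP1-MAML2 vs GFP the real grouping called 741 genes higher, 574 lower and 4 lists, and the other groupings at most 0, 0 and 4, so the number of groupings with at least the real count was 1, 1 and 4. For S94A-YAP1-MAML2 vs GFP the real counts were 7, 5 and 6, the highest others 2, 34 and 5, and the numbers 1, 2 and 1. The grouping with 34 lower genes mixes the plasmids, and whether these are false calls or come from another difference between the libraries was not tested. For wtYAP1 vs GFP the real counts were 201, 115 and 11, the highest others 0, 0 and 3, and the numbers 1, 1 and 1. For YAP1-MAML2 vs S94A-YAP1-MAML2 they were 711, 469 and 4, then 0, 1 and 8, then 1, 1 and 4. For YAP1-MAML2 vs wtYAP1 they were 290, 192 and 5, then 1, 0 and 5, then 1, 1 and 2.

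Against GFP, few genes changed with S94A-YAP1-MAML2, whose plasmid RNA was also lower than that of YAP1-MAML2. Against wtYAP1, a contrast outside the 5 comparisons, edgeR called 721 genes higher and 733 lower with S94A-YAP1-MAML2. That contrast is between different plasmids, so it does not measure the S94A change alone. If genes answered in proportion to plasmid RNA, they would reach the share of the YAP1-MAML2 rise that MAML2 reached, 17.5% (16.9 to 18.1% over libraries). Over the 52 genes at least 2-fold higher with YAP1-MAML2 the median was 5.08% (bootstrap 95% interval 0.919 to 14.9%, genes resampled), with CCN2 at 0.422% and ANKRD1 at 0.977%, while 17 genes reached the MAML2 share. The interval lay below the MAML2 range by a small margin. These genes were chosen for their rise in the same YAP1-MAML2 libraries, and 20 of them had a GFP mean under 0.1 CPM. Resampling genes does not measure the spread between libraries. Whether the answer was proportional therefore cannot be told. An answer steeper than in proportion also stays open, since each form was measured at 1 level and these lie 5.67-fold apart. The S94A change, which removes a contact with TEAD, is the biological explanation the design offers, and it cannot be separated from that difference in level.

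Many genes changed by little with YAP1-MAML2 against GFP, and fold changes followed GC content (Spearman rho 0.49) and length (-0.28). With that trend removed, 398 of 1116 calls under 1.5-fold were kept, their median absolute log2 fold change went from 0.175 to 0.123 with a median SE of 0.045 and 0.041, and whether the trend is technical or part of the response cannot be told. Of 68 calls of at least 2-fold 57 were kept. Medians of genes grouped by GC content spanned only -0.078 to 0.085 on the log2 scale, far less than 2-fold. Most of these calls would thus be kept whatever their cause. The 11 others had a median absolute log2 fold change of 1.66 before and 1.56 after, with an SE of 0.51 before and after. The highest unadjusted p called by edgeR went from 0.00354 to 0.00198, and 8 of the 11 still had a p of at most 0.00354 after, so the stricter bar accounts for those 8 and not for all. A change in the cells due to the fusion is the biological explanation, which these libraries cannot separate from handling for the small changes.

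Both fusions shared changes absent with wtYAP1, such as more mitochondrially encoded mRNA, with counts uncertain for nuclear copies, and less DNAH17. Sample numbers ran from 50 to 55 for GFP and wtYAP1 and from 62 to 67 for the fusions, and the lowest mitochondrial share in a fusion library, 3.24%, lay above the highest elsewhere, 2.88%, so handling as 2 series cannot be told apart from the fusions. The MAML2 part of both fusions is the biological explanation. DNAH17 was lower in the form with more MAML2 RNA (-1.03 ± 0.25, adjusted p = 0.00645), while the mitochondrial list was not called between the fusions after GC and length correction (camera adjusted p = 0.123), so this too cannot be told.

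The rise of YAP1 over GFP, in CPM, was 2.86% of the rise of MAML2 with YAP1-MAML2 and 2.83% with S94A-YAP1-MAML2. Whether all reads of the YAP1 part of the fusions were counted is not known.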
